A study of Nothobranchius furzeri with 9 samples.

How the data were processed

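The series holds bulk liver RNA sequencing of 9 male African turquoise killifish (*Nothobranchius furzeri*) of the wild-type GRZ strain, 3 at each of 3 ages. Per the labels, RNA was extracted with TRIzol, treated with DNase I and cleaned on RNeasy columns, and libraries were made with the SMART-Seq mRNA Kit. The submitters' processing notes name DRAGEN without a version or a role. The aligner settings, the genome build and the annotation release are not given in the sources used here. Gene positions below are printed as the deposited table gives them.

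The deposited table has 25475 Ensembl genes with 2 values per library. Per the file headers, 1 value is an estimated count, an expected count of reads that the authors made for each gene without scaling between libraries. The other, per the file headers, is TPM, which the authors scaled for gene length and to the same sum in each library, and which was not used for any test here. Between 93.6% and 95.7% of the estimated counts of a library, zeros included, were whole numbers exactly as deposited, and all were rounded before testing, which changed no value by more than 0.5. Symbols came from the table for 14724 genes and, by Entrez number, from a RefSeq gene table for 721 more. No symbol was found for 10030 genes, of which 1722 had a description. In 21 genes the table gave a clone name in shortened form. Every column of values was matched to a library, and 4311 genes had no count in any.

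Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the 3 ages, which left 13971 genes, and libraries were scaled with TMM factors. A quasi-likelihood model (glmQLFit, robust) with 1 mean for each age was fitted to all 9 libraries, and 3 contrasts were tested with glmQLFTest: adult against young, old against adult and old against young. The p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p under 0.05 counted as changed. Each log2 fold change is given with a standard error, taken as its size divided by the square root of the F statistic. Abundances are counts scaled to the TMM-adjusted library size (CPM), as mean ± SD of 3 libraries. The common biological coefficient of variation was 0.61.

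A fold change against an age without a count of the gene is given as a lower bound, from 3 counts over that age's summed library sizes. Those 3 counts are 0.0326 CPM in young, 0.042 CPM in adult and 0.0508 CPM in old. Where an age had 1 to 3 counts, the ratio of the summed counts is given with a 95% interval. Shares of a library's counts have 95% Wilson intervals. These intervals and lower bounds cover counting error only. The interval of a list median comes from resampling the member genes of the list, and measures neither counting error nor the spread between fish.

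Before the data were examined, 44 gene lists with 1801 symbols were written, for liver metabolism, immune and stress responses, senescence, growth, organelles and the cell types that a liver sample could hold. The 43 lists with at least 5 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01, on log2 CPM with a prior count of 2. Their p-values were adjusted over the lists within each comparison. The germ cell and gonad list had fewer tested members and was not tested. Beside each list stand the number of members past the gene test over all genes and, where it differs, the number adjusted over the list alone. The median log2 fold change of a list is over its tested members.

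Named genes followed a rule fixed at the same time. It takes up to 8 genes higher and 8 lower by fold among those with adjusted p under 0.05, with no overlap between the libraries of the 2 ages, at least 10 CPM in the higher age and a symbol or description. It takes up to 4 members with the smallest adjusted p of each list that changed or had at least 3 changed members, of which the text prints some. It also takes known senescence and ageing genes whatever their values, some of which are not reported here, and the 3 most abundant members of each list for another cell type. Other genes named from the short lists of changed genes, and those named under an alternative fit, were chosen after their values were seen.

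The alternatives fixed at the same time were median-of-ratios (RLE) scaling, library size only, upper-quartile scaling, TMM without the 20 most abundant genes, no filter on low counts, a filter at 10 CPM, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, only the 2 ages compared, the replicate number as a block, glmTreat at 1.5-fold and each of the 9 libraries left out in turn. For lists they were an estimated correlation, fry, library size only, the replicate block and the libraries left out. Chosen after seeing the data were removal of rRNA and mitochondrial genes, voom with quality weights, the rRNA share as a covariate, the 2-age fit for lists, and a test of gene ontology terms of the deposited table. Where the text gives an alternative's adjusted p for a gene, the lowest and highest over that gene's alternatives stand beside it.

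The pipeline was tested on simulated data with the spread of the 9 libraries. For old against young it recovered 0, 12, 42 and 60% of genes changed by 2, 4, 8 and 16-fold, and 3 of 60 calls were false. For adult against young these were 0, 18, 36 and 74%, with 5 of 69 calls false, and for old against adult 0, 22, 62 and 66%, with 8 of 83 calls false. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.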

Results

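Liver RNA was sequenced from male fish of the GRZ strain of the African turquoise killifish, an inbred vertebrate with a very short life span, at 6 weeks (young), 12 weeks (adult) and 23 to 24 weeks (old). Each age had 3 libraries. Nothing but the labels says that the replicates are separate fish. The p-values of single genes measure the spread between these samples. Those of camera with the preset correlation set the genes of a list against other genes and do not measure that spread. Total estimated counts were 21674590, 33951438 and 22603384 in the young libraries, 26890914, 22079423 and 26974448 in the adult libraries and 19600325, 19923417 and 23296247 in the old libraries. Between 15710 and 17369 genes had a count in a library.

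Genes annotated as ribosomal RNA took 2.22, 2.51 and 2.38% of the counts of the adult libraries and 21.98, 15 and 7.07% of those of old replicates 1, 2 and 3. In the young libraries they took 29.65% in replicate 1 (95% Wilson interval 29.63 to 29.67%), 4.52% in replicate 2 (4.52 to 4.53%) and 4.74% in replicate 3 (4.73 to 4.75%). The adult intervals were 2.21 to 2.22, 2.5 to 2.52 and 2.37 to 2.38%. Those of the old libraries were 21.97 to 22, 14.99 to 15.02 and 7.05 to 7.08%. In every library most of this share came from mitochondrial ribosomal RNA. Mitochondrial and nuclear ribosomal RNA genes took 27.58 and 2.07% in young replicate 1 and 19.2 and 2.78% in old replicate 1. In adult replicate 1 they took 1.98 and 0.23%. The labels give no RNA integrity values, so the share is not a direct measure of RNA quality. Young replicate 1 stood apart from the other young libraries. Its log2 CPM correlated at r = 0.753 and 0.808 with them and at 0.795, 0.82 and 0.819 with the old libraries, while young replicates 2 and 3 correlated at 0.904. The 3 adult libraries correlated with each other at 0.948 to 0.952 and the old ones at 0.816 to 0.857.

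**Figure D1:**
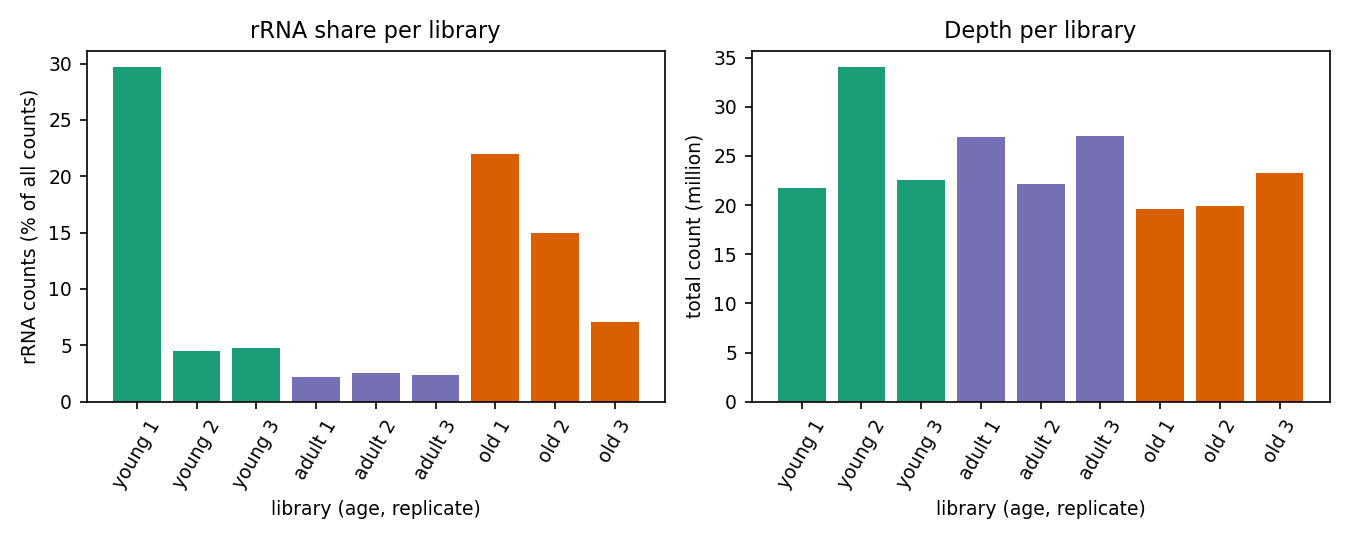
Share of counts from ribosomal RNA genes and total estimated count in each of the 9 libraries.

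**Figure D2:**
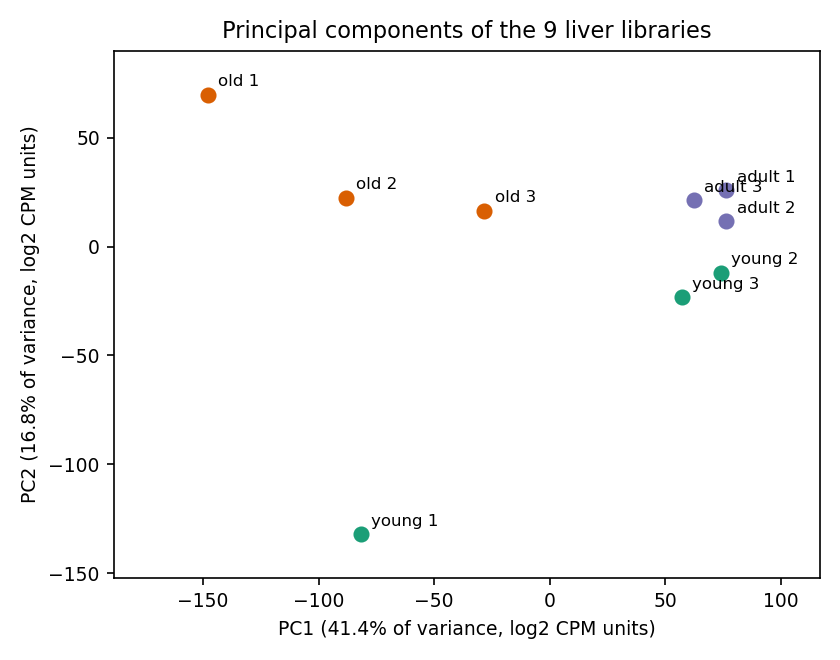
Principal components of log2 CPM of the 9 libraries. The first component held 41.4% and the second 16.8% of the variance.

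Between young and adult fish, a secreted protease and an aquaporin rose in the liver. HTRA1B (ENSNFUG00015004780, chromosome 12, 10824105 to 10865694, genome build not given in the sources used here), which encodes a secreted serine protease that cleaves matrix proteins, rose from 0.863 ± 0.451 to 69.9 ± 48.7 CPM (SD, n = 3 per age). Its log2 fold change was 6.34 ± 0.66 (SE, edgeR adjusted p = 0.0158). A gene described as aquaporin-9-like (ENSNFUG00015023172, chromosome 13, 18441388 to 18445154), of a family of glycerol and water channels, rose from 0.531 ± 0.378 to 28.8 ± 6.05 CPM. Its log2 fold change was 5.71 ± 0.57 (edgeR adjusted p = 0.0158). These 2 genes, higher in adult fish, were all that changed in edgeR among 13971 tested, and 1363 genes had an unadjusted p under 0.05. Neither call held when any old library was left out, where edgeR gave each an adjusted p of 0.0548 without old replicate 1, 0.0576 without old replicate 2 and 0.0581 without old replicate 3. HTRA1B also lost its call without young replicate 2 (adjusted p 0.0531) and young replicate 3 (0.0732), and the aquaporin gene without adult replicate 3 (0.0627, edgeR). Over all alternatives the adjusted p ran from 4.14e-23 to 0.266 for HTRA1B and from 3.96e-23 to 0.266 for the aquaporin gene. The number of changed genes was 6 without young replicate 1, 12 without adult replicate 2, 1 without young replicate 3 or adult replicate 3, and 0 without any 1 old library. DESeq2 called 397 genes, limma-voom 9, edgeR without a filter on low counts 13, and edgeR on the 2 ages alone 0, with 1386 at an unadjusted p under 0.05.

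The exocrine pancreas and pancreatic islet lists were higher in adult than in young samples, the islet genes in adult replicates 1 and 3 and not in replicate 2. In many bony fish, pancreatic tissue lies along or within the liver. Of 18 exocrine pancreas genes, 17 were higher in adult fish, with a median log2 fold change of 5.07. The list rose (camera adjusted p = 1.24e-20), with adjusted p = 0.246 with an estimated correlation. No member passed the edgeR test over all genes, and 16 did when adjusted over the list alone. The elastase gene ela2, which encodes a digestive protease, had 133 ± 91.5 CPM in young and 4397 ± 4413 CPM in adult fish (log2 5.04 ± 0.91, edgeR adjusted p = 0.119). The most abundant members, ENSNFUG00015003282 (trypsin-3-like), prss1 and CELA1, had 6733 ± 6951, 6551 ± 6605 and 5689 ± 6111 CPM in adult fish. The list summed to 101800, 8158 and 31120 CPM in adult replicates 1, 2 and 3 and to 521.6, 887.2 and 2837 CPM in the young ones. Of 5 pancreatic islet genes, 4 were higher in adult fish, with a median of 7.83 (camera adjusted p = 0.0344, and adjusted p = 0.361 with an estimated correlation). Adjusted over the list alone, 4 islet genes were past the threshold, against 0 over all genes. The insulin gene INS had 0.963 ± 1.38 CPM in young and 327 ± 294 CPM in adult fish (8.31 ± 2.63, edgeR adjusted p = 0.358), with 578.1, 3.01 and 399 CPM in adult replicates 1 to 3 and 0, 2.54 and 0.351 CPM in the young ones. The glucagon gene GCGB had 85.2, 0.674 and 47.8 CPM in adult replicates 1 to 3, and gcga had 50.7, 0.18 and 42.6 CPM. The islet call ended without adult replicate 1 (adjusted p 0.0829, camera) and without adult replicate 3 (0.0731), and with the ribosomal RNA share as a covariate (0.234).

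The complement, coagulation and acute phase lists rose from young to adult liver. Of 21 complement genes 19 were higher, with a median log2 fold change of 1.04 (camera adjusted p = 3.01e-09, and adjusted p = 0.0648 with an estimated correlation). Adjusted over the list alone 10 complement genes were past the threshold, against 0 over all genes. The membrane attack gene c9 had 3166 ± 1370 CPM in young and 11050 ± 2178 CPM in adult fish (1.80 ± 0.37, edgeR adjusted p = 0.137). The protease gene c1r, which starts the classical pathway, had 203 ± 88.7 and 931 ± 114 CPM (2.2 ± 0.43, edgeR adjusted p = 0.137). Of 19 coagulation and fibrinolysis genes 18 were higher, with a median of 0.77 (camera adjusted p = 1.71e-06, and adjusted p = 0.279 with an estimated correlation). Of these, 0 passed over all genes and 5 adjusted over the list alone. Prothrombin, F2, had 3218 ± 1107 and 7887 ± 725 CPM (1.29 ± 0.36, edgeR adjusted p = 0.311). Acute phase and iron protein genes were higher in 21 of 29 members, with a median of 0.50 (camera adjusted p = 0.00674, and adjusted p = 0.279 with an estimated correlation), with 4 past the threshold adjusted over the list alone and 0 over all genes. The transferrin receptor gene TFR1A, which serves iron uptake, had 76.6 ± 25.1 and 329 ± 193 CPM (2.103 ± 0.44, edgeR adjusted p = 0.141). With the ribosomal RNA share as a covariate the acute phase call ended (adjusted p 0.101, camera).

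Macrophage, neutrophil, T and NK cell, endothelial and fibroblast markers and interferon genes were also higher as lists in adult than in young samples. Macrophage markers were higher in 20 of 23 members, with a median of 1.47 (camera adjusted p = 1.71e-06, and adjusted p = 0.183 with an estimated correlation), and 5 passed adjusted over the list alone against 0 over all genes. C1QA, a complement subunit made by macrophages, had 1.12 ± 0.872 and 8.27 ± 2.42 CPM, and the growth factor receptor gene csf1ra had 0.613 ± 0.557 and 7.36 ± 3.57 CPM. The interferon response and antigen presentation list was higher in 20 of 24 members, with a median of 0.52 (camera adjusted p = 1.42e-05, and adjusted p = 0.279 with an estimated correlation), and 4 passed adjusted over the list alone against 0 over all genes. Neutrophil markers were higher in 10 of 15 members, with a median of 1.08 (camera adjusted p = 0.012, and adjusted p = 0.279 with an estimated correlation). The neutrophil peroxidase gene mpx had 4.10 ± 1.58 and 93.4 ± 145 CPM, with 260.4, 8.27 and 11.43 CPM in adult replicates 1, 2 and 3. T and NK cell markers were higher in 6 of 7 members, with a median of 0.75 (camera adjusted p = 0.017, and adjusted p = 0.279 with an estimated correlation), and 2 passed adjusted over the list alone against 0 over all genes. Endothelial markers were higher in 20 of 28 members, with a median of 0.53 (camera adjusted p = 0.0399, and adjusted p = 0.279 with an estimated correlation). The vascular growth factor receptor gene kdr had 7.44 ± 1.60 and 20.4 ± 0.695 CPM. The 3 most abundant endothelial members, PTPRB, CLDN5B and APLNRB, had 17.57, 24.64 and 13.72 CPM in young and 18.98, 10.99 and 20.83 CPM in adult fish. Fibroblast, stellate and matrix genes were higher in 30 of 47 members, with a median of 0.54 (camera adjusted p = 0.0114, and adjusted p = 0.446 with an estimated correlation), and 3 passed adjusted over the list alone against 0 over all genes. Fibronectin, FN1B, a matrix glycoprotein, had 1489 ± 290 and 3287 ± 355 CPM (1.14 ± 0.27, edgeR adjusted p = 0.216). Without young replicate 2 the camera calls of the endothelial (adjusted p 0.186) and fibroblast lists (0.269) ended. The fibroblast call also ended without adult replicate 1 (0.172, camera), and the neutrophil call without young replicate 3 (0.0567). Adult replicate 1, in which exocrine pancreas genes summed to 101800 CPM against 8158 and 31120 CPM in replicates 2 and 3, had the highest adult list medians of the cell type markers in this paragraph, with each gene centred on its mean over all libraries. In adult replicates 1 to 3 they were 0.93, 0.27 and 0.19 for fibroblast genes, 1.08, 0.5 and 0.41 for macrophage, 0.74, -0.06 and 0.4 for neutrophil, 0.42, 0.21 and 0.34 for endothelial and 0.51, 0.47 and 0.38 for T and NK cell markers. Those of the interferon list were 0.39, 0.6 and 0.01. The calls of endothelial (adjusted p 0.238, camera) and T and NK cell markers (0.492) ended with the ribosomal RNA share as a covariate.

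The amino acid, xenobiotic, glycolysis and bile acid lists also rose between young and adult. Amino acid and nitrogen metabolism genes were higher in 41 of 54 members, with a median of 0.70 (camera adjusted p = 9.09e-09, and adjusted p = 0.246 with an estimated correlation), and 12 passed adjusted over the list alone against 0 over all genes. CBS, the first enzyme of transsulfuration, had 116 ± 74.8 and 874 ± 152 CPM (2.91 ± 0.51, edgeR adjusted p = 0.119). Xenobiotic metabolism genes were higher in 25 of 33 members, with a median of 0.50 (camera adjusted p = 0.00379, and adjusted p = 0.279 with an estimated correlation), and 2 passed adjusted over the list alone against 0 over all genes. CYP1A, a target of the aryl hydrocarbon receptor, had 49.6 ± 17.8 and 236 ± 34.0 CPM (2.25 ± 0.42, edgeR adjusted p = 0.13). Glycolysis and gluconeogenesis genes were higher in 31 of 47 members, with a median of 0.56 (camera adjusted p = 0.00522, and adjusted p = 0.246 with an estimated correlation). Adjusted over the list alone 1 member was lower, against 0 over all genes, and this was pfkfb4b, which sets the level of an activator of glycolysis (-2.13 ± 0.44, edgeR adjusted p = 0.141). The bile acid synthesis and transport list was higher in 12 of 19 members, with a median of 0.45 (camera adjusted p = 0.0121, and adjusted p = 0.309 with an estimated correlation), and 2 passed adjusted over the list alone against 0 over all genes. Its member fgf19, a hormone that lowers bile acid synthesis, had 0.081 ± 0.14 and 12.2 ± 10.6 CPM (6.80 ± 1.02, edgeR adjusted p = 0.0961). Without young replicate 2 (adjusted p 0.0733, camera) or adult replicate 2 (0.0531) the bile acid call ended. The bile acid (adjusted p 0.418, camera) and xenobiotic calls (0.136) ended with the ribosomal RNA share as a covariate.

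Lists of hormonal signalling, the clock and the lysosome had small medians in the same comparison. Circadian clock genes were higher in 27 of 38 members, with a median of 0.31 (camera adjusted p = 0.00674, and adjusted p = 0.279 with an estimated correlation). Lysosome and autophagy genes were higher in 39 of 69 members, with a median of 0.2 (camera adjusted p = 0.0267, and adjusted p = 0.663 with an estimated correlation), and 1 passed adjusted over the list alone against 0 over all genes. This was man2b1, a lysosomal mannosidase, with 25.9 ± 9.79 and 114 ± 32.1 CPM (2.14 ± 0.36, edgeR adjusted p = 0.119). The growth hormone, IGF and insulin list was higher in 26 of 50 members, with a median of 0.12 (camera adjusted p = 0.0408, and adjusted p = 0.333 with an estimated correlation), and 1 passed adjusted over the list alone against 0 over all genes. This was IGF1, the main circulating growth factor of the liver, with 5.32 ± 0.659 and 17.3 ± 1.73 CPM (1.70 ± 0.29, edgeR adjusted p = 0.119). Without young replicate 2 the camera calls of the circadian (adjusted p 0.295), lysosome (0.295) and growth hormone lists (0.639) ended. The lysosome call also ended without adult replicate 3 (0.112, camera), with library size scaling (0.0996) and with the ribosomal RNA share as a covariate (0.962). The growth hormone call also ended without adult replicate 3 (0.0629), old replicate 1 (0.0906) and old replicate 3 (0.0594, camera), and on the 2 ages alone (0.105).

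The lists of ribosomes and of oxidative phosphorylation fell from young to adult in camera, and for 3 of the 4 lists this went with young replicate 1. In edgeR 0 genes of any list were lower over all genes, and none of these list calls held with an estimated correlation. Cytosolic ribosomal protein genes were lower in 78 of 81 members, with a median of -0.88 (camera adjusted p = 3.01e-09, and adjusted p = 0.613 with an estimated correlation). RPLP0, a stalk protein of the large subunit, had 2298 ± 2132 and 552 ± 18.3 CPM (-2.06 ± 0.58, edgeR adjusted p = 0.312). Without young replicate 1, the library with 29.65% ribosomal RNA, the median was -0.13 and the call ended (camera adjusted p 0.107). Nuclear genes of oxidative phosphorylation were lower in 64 of 80 members, with a median of -0.49 (camera adjusted p = 9.65e-06, and adjusted p = 0.559 with an estimated correlation). Their median was -0.12 without young replicate 1 and the call ended (camera adjusted p 0.0572). The 13 mitochondrially encoded genes were lower in 13 members, with a median of -1.52 (camera adjusted p = 0.0036, and adjusted p = 0.613 with an estimated correlation). COX1, a subunit of cytochrome c oxidase, had 13150 ± 15570 and 3585 ± 376 CPM (-1.88 ± 0.71, edgeR adjusted p = 0.444). The median of the mitochondrially encoded genes was 0.0 without young replicate 1 and the call ended (camera adjusted p 0.748). With the ribosomal RNA share as a covariate the direction turned for 3 lists in camera, with the cytosolic ribosomal proteins (adjusted p 7.34e-08) and the mitochondrially encoded genes (1.06e-06) higher in adult and oxidative phosphorylation past the threshold in neither direction (0.492). Over all alternatives, in whichever direction, the camera adjusted p ran from 1e-15 to 0.613 for the cytosolic ribosomal proteins, from 9.26e-09 to 0.559 for oxidative phosphorylation and from 1.06e-06 to 0.748 for the mitochondrially encoded genes. Mitochondrial protein-coding genes took 7.22, 1.35 and 1.49% of the counts of young replicates 1, 2 and 3. Most of the ribosomal RNA share also came from mitochondrial genes, so as a covariate it cannot decide about the mitochondrially encoded genes. Mitochondrial ribosomal proteins were lower in 66 of 70 members, with a median of -0.38 (camera adjusted p = 1.42e-05, and adjusted p = 0.279 with an estimated correlation).

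In all, 22 of 43 lists changed between young and adult in camera, 18 higher and 4 lower, and 0 did with an estimated correlation, while fry called 9. Calls of 11 of these 22 lists held with each library left out.

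Between adult and old fish, an enzyme of the citric acid cycle fell in the liver. The gene ENSNFUG00015017190 (chromosome 2, 37089303 to 37128342), described as oxoglutarate dehydrogenase b, which converts 2-oxoglutarate to succinyl-CoA, fell from 368 ± 56.7 to 50.6 ± 6.25 CPM (n = 3 per age). Its log2 fold change was -2.86 ± 0.28 (edgeR adjusted p = 0.0137). It was the 1 gene that changed in edgeR among 13971 tested, while 3158 genes had an unadjusted p under 0.05 and 273 an adjusted p under 0.10. Its call ended without adult replicate 1 (adjusted p 0.063, edgeR), adult replicate 3 (0.121), old replicate 1 (0.0677) and old replicate 2 (0.146), and over all alternatives its adjusted p ran from 2.07e-25 to 0.146. Fitted without the young libraries, edgeR called 1682 genes between adult and old, 971 higher and 711 lower. Without young replicate 1 alone it called 1625, 839 higher and 786 lower, of which 1448 were shared and had the same sign. On the 1682 genes, placed from 0 at the adult mean to 1 at the old mean, young replicate 1 lay at a median of 1.01 (quartiles 0.65 to 1.31), replicate 2 at 0.04 and replicate 3 at 0.18. The count was 28 without adult replicate 2, 269 without old replicate 3 and 0 without adult replicate 1, adult replicate 3, old replicate 1 or old replicate 2. DESeq2 called 1903 genes, edgeR without a filter on low counts 74, and limma-voom with quality weights 3072.

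Under the fit without the young libraries, GADD45BA and slc25a25a, named here after their values were seen, were among the largest increases. GADD45BA, a growth arrest gene induced by stress, had 6.02 ± 2.92 CPM in adult and 133 ± 78.3 CPM in old fish (log2 4.49 ± 0.61, edgeR adjusted p = 0.0161). With all 9 libraries its adjusted p was 0.0761 in edgeR, with a range over its alternatives of 7.97e-07 to 0.453. The mitochondrial carrier gene slc25a25a, which exchanges ATP and phosphate, had 10.4 and 201 CPM (4.31, edgeR adjusted p = 0.015, with a range over its alternatives of 7.97e-07 to 0.495).

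The cell cycle and DNA damage lists fell between adult and old liver. Of 91 cell cycle and DNA replication genes 77 were lower, with a median log2 fold change of -1.78 (camera adjusted p = 1.14e-11, and adjusted p = 0.476 with an estimated correlation). No member passed edgeR over all genes, and adjusted over the list alone 20 were lower and 2 higher. The condensin gene ncapg, which compacts chromosomes in mitosis, had 2.42 ± 0.413 CPM in adult fish and no count in old ones, at least 47.7-fold less (edgeR adjusted p = 0.0634). DNA damage response and repair genes were lower in 38 of 56 members, with a median of -0.5 (camera adjusted p = 0.0429, and adjusted p = 0.866 with an estimated correlation). The base excision repair gene apex1 had 17.8 ± 1.23 and 7.69 ± 2.57 CPM (-1.21 ± 0.35, edgeR adjusted p = 0.115). The DNA damage call ended without young replicate 1 (adjusted p 0.0591, camera), adult replicate 2 (0.116) and old replicate 1 (0.119), on the 2 ages alone (0.0916) and with the ribosomal RNA share as a covariate (0.381). By library the cell cycle median, with each gene centred on its mean over all libraries, was -2.19, -1.58 and -0.34 in old replicates 1 to 3, in which ribosomal RNA took 21.98, 15 and 7.07%.

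The cholesterol, fatty acid and endoplasmic reticulum stress lists also fell between adult and old liver. Cholesterol synthesis and uptake genes were lower in 33 of 34 members, with a median of -1.35 (camera adjusted p = 6.2e-07, and adjusted p = 0.866 with an estimated correlation), and 15 passed adjusted over the list alone against 0 over all genes. Squalene epoxidase, sqlea, a rate-limiting enzyme of sterol synthesis, had 117 ± 66.9 and 7.05 ± 2.76 CPM (-4.05 ± 0.96, edgeR adjusted p = 0.0949). Fatty acid and triglyceride synthesis genes were lower in 24 of 35 members, with a median of -0.67 (camera adjusted p = 0.0143, and adjusted p = 0.866 with an estimated correlation), and 1 was lower adjusted over the list alone against 0 over all genes. This was ACACA, which makes malonyl-CoA, with 216 ± 62.2 and 49.6 ± 8.42 CPM (-2.12 ± 0.48, edgeR adjusted p = 0.0945). Fatty acid oxidation and PPAR target genes were lower in 36 of 51 members, with a median of -0.63 (camera adjusted p = 0.0143, and adjusted p = 0.866 with an estimated correlation). HADHAB, a subunit of the mitochondrial trifunctional protein, had 132 ± 10.5 and 31.0 ± 12.4 CPM (-2.09 ± 0.52, edgeR adjusted p = 0.102). Endoplasmic reticulum stress genes were lower in 34 of 46 members, with a median of -1.05 (camera adjusted p = 0.00687, and adjusted p = 0.866 with an estimated correlation), and adjusted over the list alone 8 were lower and 1 higher against 0 over all genes. The chaperone gene HYOU1 had 183 ± 37.3 and 31.4 ± 9.63 CPM (-2.54 ± 0.60, edgeR adjusted p = 0.0949). Without old replicate 2 the camera calls of the fatty acid synthesis (adjusted p 0.0734) and oxidation lists (0.0979) ended. With the ribosomal RNA share as a covariate the camera calls of the cholesterol (adjusted p 0.084), fatty acid synthesis (0.923) and fatty acid oxidation lists (0.857) ended, and so did that of the endoplasmic reticulum stress list (0.923, with the direction of the camera test turned). Over all alternatives the camera adjusted p of these 4 lists ran from 6.97e-09 to 0.866, from 0.00205 to 0.923, from 0.0009 to 0.866 and from 0.00129 to 0.923. The cholesterol list had library medians, with each gene centred on its mean over all libraries, of -1.26, -1.68 and -0.47 in old replicates 1 to 3, 0.83, 0.62 and -0.02 in adult ones and -0.18, 0.88 and 1.63 in young ones. Ribosomal RNA took 21.98, 15 and 7.07% of counts in old replicates 1 to 3, 2.22 to 2.51% in adult libraries and 29.65, 4.52 and 4.74% in young replicates 1 to 3. The adult and old shares do not overlap, so between these ages the covariate cannot separate the share from age.

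The cytosolic ribosomal protein, oxidative phosphorylation and mitochondrially encoded lists rose between adult and old, along with the share of ribosomal RNA. Cytosolic ribosomal protein genes were higher in 78 of 81 members, with a median of 1.37 (camera adjusted p = 4.89e-19, and adjusted p = 0.866 with an estimated correlation), and 67 passed adjusted over the list alone against 0 over all genes. RPLP0 had 552 ± 18.3 and 3197 ± 1115 CPM (2.53 ± 0.59, edgeR adjusted p = 0.0949), and RPL5, a large-subunit protein that binds 5S RNA, had 276 ± 10.3 and 924 ± 274 CPM (1.74 ± 0.42, 0.0981). Nuclear genes of oxidative phosphorylation were higher in 60 of 80 members, with a median of 0.42 (camera adjusted p = 0.0024, and adjusted p = 0.97 with an estimated correlation). Mitochondrially encoded genes were higher in 13 of 13, with a median of 1.17 (camera adjusted p = 0.00501, and adjusted p = 0.97 with an estimated correlation). COX1 had 3585 ± 376 and 9847 ± 2926 CPM (1.46 ± 0.70, edgeR adjusted p = 0.248). Ribosomal RNA took 2.22 to 2.51% of the counts in adult and 7.07 to 21.98% in old libraries. With that share as a covariate the ribosomal protein (adjusted p 0.879, camera) and oxidative phosphorylation lists (0.0761) lost their calls, each with the direction of the test turned. The mitochondrially encoded genes were then lower in old fish (4.41e-08, camera). Most of that share is mitochondrial ribosomal RNA, from the same genome as these genes, so the covariate cannot decide about them. Over all alternatives, in whichever direction, the camera adjusted p of these 3 lists ran from 3.15e-24 to 0.879, from 0.00019 to 0.97 and from 4.41e-08 to 0.97. Immediate early genes were higher in 29 of 36 members, with a median of 0.73 (camera adjusted p = 0.000606, and adjusted p = 0.476 with an estimated correlation), and 6 passed adjusted over the list alone against 0 over all genes. The growth factor gene HBEGFA, a ligand of the EGF receptor, had 2.54 ± 0.637 and 11.6 ± 3.87 CPM (2.19 ± 0.47, edgeR adjusted p = 0.0873).

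The exocrine pancreas, erythrocyte and fibroblast lists fell between adult and old samples. Exocrine pancreas genes were lower in 17 of 18 members, with a median of -5.56 (camera adjusted p = 1.23e-11, and adjusted p = 0.866 with an estimated correlation), and adjusted over the list alone 16 were lower and 1 higher against 0 over all genes. The list summed to 1390, 690.4 and 861.8 CPM in the old libraries, and ela2 had 95.2 ± 33.2 CPM (-5.53 ± 0.93, edgeR adjusted p = 0.075). Erythrocyte genes were lower in 18 of 23 members, with a median of -0.73 (camera adjusted p = 0.0345, and adjusted p = 0.866 with an estimated correlation). The gene ENSNFUG00015007606, a beta globin, had 1868 ± 389 and 872 ± 166 CPM (-1.10 ± 0.33, edgeR adjusted p = 0.116). Fibroblast, stellate and matrix genes were lower in 31 of 47 members, with a median of -0.81 (camera adjusted p = 0.0429, and adjusted p = 0.866 with an estimated correlation), and 5 were lower adjusted over the list alone against 0 over all genes. Their adult medians, with each gene centred on its mean over all libraries, were 0.93, 0.27 and 0.19 in replicates 1 to 3, in which exocrine pancreas genes summed to 101800, 8158 and 31120 CPM. The collagen gene COL5A2, which limits fibril width, had 16.2 ± 4.89 and 4.84 ± 1.89 CPM (-1.74 ± 0.42, edgeR adjusted p = 0.101). The most abundant members did not fall alike, with FN1B at 3287 ± 355 and 3039 ± 653 CPM. The MFAP4 genes ENSNFUG00015006349 and ENSNFUG00015008015 had 275 ± 132 and 232 ± 177 CPM in adult fish. In old fish they had 489 ± 265 and 319 ± 201 CPM. The whole list summed to 4461 ± 641 CPM in adult and 4224 ± 218 CPM in old libraries. The erythrocyte call ended without young replicate 1 (adjusted p 0.0591, camera), adult replicate 3 (0.0995) and old replicate 2 (0.102), and with the ribosomal RNA share as a covariate (0.0798). The fibroblast call ended without young replicate 1 (0.0591), adult replicate 1 (0.143) and old replicate 3 (0.0653, camera), and with the replicate number as a block (0.0556).

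In all, 13 lists changed between adult and old in camera, 4 higher and 9 lower, and 0 did with an estimated correlation, while fry called 6. Calls of 8 of these 13 lists held with each library left out.

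Between young and old fish, 78 genes changed in the liver, 48 higher and 30 lower, in edgeR on 13971 genes. HTRA1B rose to 404 ± 88.2 CPM in old fish (n = 3), a log2 fold change of 8.87 ± 0.73 (edgeR adjusted p = 0.00367). The lectin gene cldc1 (ENSNFUG00015001775, chromosome 5, 61546468 to 61550643), described as similar to a receptor of myeloid cells, rose from 0.684 ± 0.425 to 1614 ± 1254 CPM (11.26 ± 1.61, edgeR adjusted p = 0.0161). The hormone gene fgf19 (ENSNFUG00015017951, scaffold LN602067.1, 12015 to 30146) rose from 0.081 ± 0.14 to 54.95 ± 2.05 CPM (8.98 ± 1.09, edgeR adjusted p = 0.0125). The condensin gene ncapg (ENSNFUG00015000473) fell from 5.10 ± 0.72 CPM to no count, at least 100-fold (edgeR adjusted p = 0.0125). A proline dehydrogenase 1a gene (ENSNFUG00015009075, chromosome 2, 51991571 to 52004766), which breaks down proline, rose from 0.254 ± 0.22 to 52.5 ± 36.4 CPM (7.54 ± 0.96, edgeR adjusted p = 0.0125). The T cell kinase gene lck (ENSNFUG00015015524, chromosome 16, 36565521 to 36582172) rose from 0.148 ± 0.178 to 14.3 ± 3.09 CPM (6.40 ± 0.80, edgeR adjusted p = 0.0125). The aquaporin-9-like gene ENSNFUG00015023172 rose to 32.3 ± 6.24 CPM (5.87 ± 0.58, edgeR adjusted p = 0.00905). The citrate transporter gene SLC13A5 (ENSNFUG00015002418, chromosome 6, 14967073 to 14975819) rose from 3.68 ± 3.70 to 178.5 ± 32.1 CPM (5.62 ± 0.77, edgeR adjusted p = 0.0137). PCDH15 (ENSNFUG00015017786), a cadherin known from hair cells, rose from 0.377 ± 0.323 to 14.5 ± 9.82 CPM (5.20 ± 0.89, edgeR adjusted p = 0.0379). IGF1 (ENSNFUG00015022671) rose to 29.9 ± 5.26 CPM (2.49 ± 0.30, edgeR adjusted p = 0.0125). Among genes that fell, si:ch211-63o20.7 (ENSNFUG00015012319), a kinase gene similar to STK35, went from 12.1 ± 4.29 CPM to no count, at least 239-fold (edgeR adjusted p = 0.0125). INHBC (ENSNFUG00015020646), of the inhibin and activin family, fell from 25.7 ± 24.8 CPM to 2 counts, a ratio of 814 (225 to 6720, edgeR adjusted p = 0.0375). The gene uhrf1 (ENSNFUG00015017248), which maintains DNA methylation through replication, fell from 14.2 ± 9.60 to 0.893 ± 0.13 CPM (-3.98 ± 0.72, edgeR adjusted p = 0.0475). The gene pfkfb4b (ENSNFUG00015015017) fell from 327.5 ± 212 to 28.8 ± 6.44 CPM (-3.51 ± 0.47, edgeR adjusted p = 0.0137). Calreticulin, calr (ENSNFUG00015023570), a chaperone of the endoplasmic reticulum, fell from 69.1 ± 38.2 to 6.71 ± 3.11 CPM (-3.36 ± 0.58, edgeR adjusted p = 0.0385). GADL1 (ENSNFUG00015017331), a decarboxylase of acidic amino acids, fell from 234 ± 116 to 24.8 ± 13.1 CPM (-3.24 ± 0.50, edgeR adjusted p = 0.0247). MAP1A (ENSNFUG00015005177), a microtubule-binding protein, fell by 2.42 ± 0.38 on the log2 scale (edgeR adjusted p = 0.0259), and slc22a2 (ENSNFUG00015004874), an organic cation transporter, by 2.39 ± 0.33 (0.0139). Without old replicate 2, 2 of the 78 genes kept their call, and the other 76 had an edgeR adjusted p of 0.0564 to 0.147. Without young replicate 3, 14 kept it (others 0.0552 to 0.145), without old replicate 1, 29 (0.0524 to 0.15), and without young replicate 2, 35 (0.0517 to 0.121). Without adult replicates 1, 2 and 3, 36, 40 and 37 kept it (others 0.054 to 0.115, 0.052 to 0.117 and 0.0644 to 0.106), without old replicate 3, 68 (others 0.0507 to 0.0724), and without young replicate 1, 78. HTRA1B (highest adjusted p 0.022, edgeR) and the aquaporin-9-like gene (0.0488) kept their calls with each library left out and under all 24 alternatives. The number of changed genes was 1321 without young replicate 1, with 627 higher and 694 lower. It was 44 and 15 without young replicates 2 and 3, and 36, 41 and 38 without adult replicates 1 to 3. Without old replicates 1 to 3 it was 34, 2 and 193. DESeq2 called 1129 genes, edgeR without a filter on low counts 131, edgeR on the 2 ages alone 6, and library size scaling 55, 27 of them higher.

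**Figure D3:**
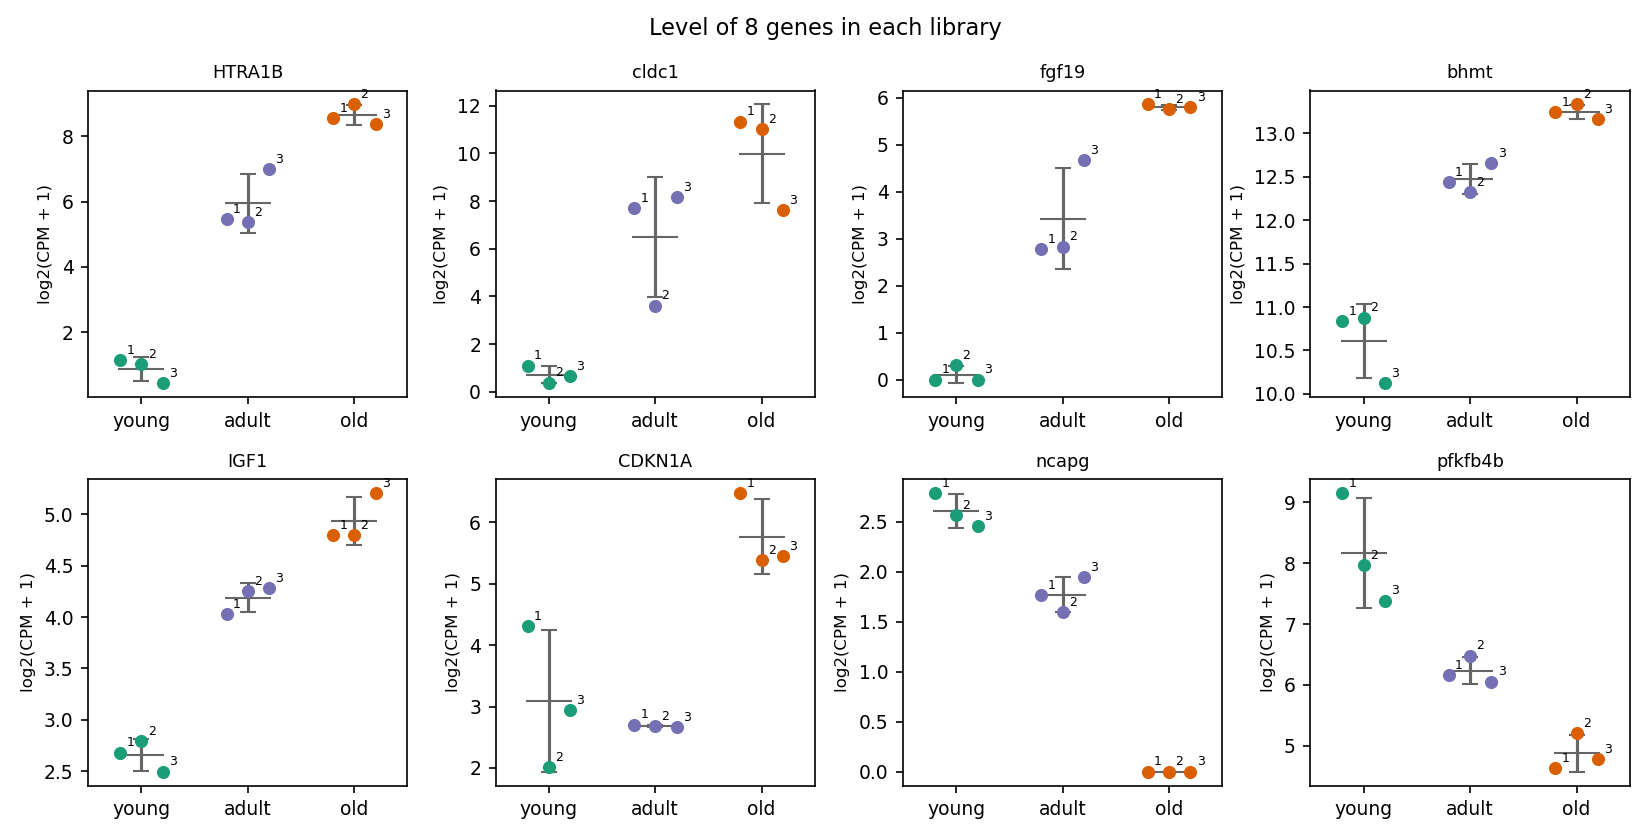
Abundance of 8 named genes in each library, as log2(CPM + 1), with the mean and SD of each age. Points are numbered by replicate.

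The amino acid and nitrogen metabolism list rose between young and old. Of 54 amino acid and nitrogen metabolism genes 38 were higher, with a median log2 fold change of 0.49 (camera adjusted p = 3.78e-05, and adjusted p = 0.416 with an estimated correlation). In edgeR 4 members rose over all genes, and adjusted over the list alone 17 were higher and 1 lower. They were bhmt, which remethylates homocysteine (1608 ± 429 to 9751 ± 566 CPM, 2.60 ± 0.29, edgeR adjusted p = 0.0106), and fah, the last enzyme of tyrosine breakdown (310 ± 35.4 to 1078 ± 28.4 CPM, 1.80 ± 0.25, 0.0137). The others were agxta, which detoxifies glyoxylate (1.58 ± 0.24, edgeR adjusted p = 0.0214), and CBS (2.85 ± 0.50, 0.0442). Without old replicate 2 these 4 edgeR calls were among those lost, at the adjusted p range of 0.0564 to 0.147.

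Cell cycle genes were lower in old than in young liver across most of the list. Of 91 cell cycle and DNA replication genes 85 were lower, with a median of -2.0 (camera adjusted p = 3.09e-20, and adjusted p = 0.155 with an estimated correlation). In edgeR 3 members fell over all genes and 16 adjusted over the list alone. These 3 were ncapg, the condensin gene smc2, which fell to 1 count (ratio 115, 20.5 to 4580, edgeR adjusted p = 0.0241), and the replication factor gene MCM10, also at 1 count (ratio 153, 27.2 to 6080, 0.0286). HMMR, a spindle protein outside the list, fell at least 58.4-fold (edgeR adjusted p = 0.0157). Without old replicate 2 these calls were lost, in the edgeR adjusted p range of 0.0564 to 0.147. DNA damage response and repair genes were lower in 44 of 56 members, with a median of -0.53 (camera adjusted p = 0.00097, and adjusted p = 0.255 with an estimated correlation), and 1 passed adjusted over the list alone against 0 over all genes. This was apex1 (-1.88 ± 0.36, edgeR adjusted p = 0.0563).

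The complement, macrophage, interferon, immediate early and coagulation lists were higher in old than in young liver, while T and NK cell markers (median 0.06, camera adjusted p = 0.177), neutrophil markers (0.59, 0.0605) and B and plasma cell markers (0.61, 0.247) did not pass the test. Neutrophil markers passed as higher in old fish without young replicate 2 (adjusted p 0.0156, camera) and without adult replicate 1 (0.0452), with library size scaling (0.0377) and on the 2 ages alone (0.047). Complement genes were higher in 17 of 21 members, with a median of 0.83 (camera adjusted p = 9.94e-05, and adjusted p = 0.155 with an estimated correlation), and 10 passed adjusted over the list alone against 0 over all genes. Macrophage markers were higher in 20 of 23 members, with a median of 1.01 (camera adjusted p = 0.000131, and adjusted p = 0.203 with an estimated correlation), and 3 passed adjusted over the list alone against 0 over all genes. C1QA, in the complement and macrophage lists, had 1.12 ± 0.872 and 13.5 ± 8.10 CPM (3.59 ± 0.72, edgeR adjusted p = 0.0633). Interferon response and antigen presentation genes were higher in 18 of 24 members, with a median of 0.86 (camera adjusted p = 0.000494, and adjusted p = 0.54 with an estimated correlation), with 2 past the threshold over all genes and 4 adjusted over the list alone. These 2 were PSMB10, an immunoproteasome subunit (5.62 ± 0.672 to 21.8 ± 5.67 CPM, 1.95 ± 0.33, edgeR adjusted p = 0.0342), and tap2a, a peptide transporter (2.30 ± 0.41, 0.0452). Without young replicate 1 both kept their edgeR calls, and without old replicate 2 neither did (0.0564 to 0.147 over the genes lost). Immediate early genes were higher in 28 of 36 members, with a median of 0.67 (camera adjusted p = 0.000318, and adjusted p = 0.155 with an estimated correlation), and adjusted over the list alone 3 were higher and 1 lower against 0 over all genes. NFKBIAB, an inhibitor of NF-kappa-B induced by it, had 17.9 ± 6.51 and 73.5 ± 33.0 CPM (2.04 ± 0.44, edgeR adjusted p = 0.0735). Coagulation and fibrinolysis genes were higher in 17 of 19 members, with a median of 0.41 (camera adjusted p = 0.0239, and adjusted p = 0.634 with an estimated correlation). The coagulation call ended without young replicate 1 (adjusted p 0.153, camera) and old replicate 3 (0.559), and with library size scaling (0.0998).

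The cholesterol, fatty acid, endoplasmic reticulum stress, proteasome and erythrocyte lists were lower in old than in young liver. Cholesterol synthesis and uptake genes were lower in 29 of 34 members, with a median of -1.82 (camera adjusted p = 7.36e-08, and adjusted p = 0.416 with an estimated correlation), and adjusted over the list alone 21 were lower and 1 higher against 0 over all genes. NSDHL, an enzyme late in the sterol pathway, had 164 ± 155 and 4.42 ± 1.41 CPM (-5.22 ± 0.99, edgeR adjusted p = 0.0563). Endoplasmic reticulum stress genes were lower in 38 of 46 members, with a median of -0.96 (camera adjusted p = 0.00097, and adjusted p = 0.634 with an estimated correlation), with 1 lower over all genes, calr, and 12 adjusted over the list alone. Fatty acid oxidation and PPAR target genes were lower in 39 of 51 members, with a median of -0.58 (camera adjusted p = 0.00537, and adjusted p = 0.634 with an estimated correlation), and adjusted over the list alone 5 were lower and 1 higher against 0 over all genes. Fatty acid and triglyceride synthesis genes were lower in 25 of 35 members, with a median of -0.8 (camera adjusted p = 0.0239, and adjusted p = 0.634 with an estimated correlation), and adjusted over the list alone 8 were lower and 1 higher against 0 over all genes. The desaturase gene scdb had 396 ± 145 and 90.9 ± 31.9 CPM (-2.12 ± 0.45, edgeR adjusted p = 0.071). Proteasome genes were lower in 35 of 40 members, with a median of -0.56 (camera adjusted p = 0.0115, and adjusted p = 0.649 with an estimated correlation). Erythrocyte genes were lower in 17 of 23 members, with a median of -0.78 (camera adjusted p = 0.0215, and adjusted p = 0.634 with an estimated correlation), and adjusted over the list alone 5 were lower and 1 higher against 0 over all genes. The fatty acid synthesis call ended without young replicate 2 (adjusted p 0.0635, camera), young replicate 3 (0.0858) and old replicate 2 (0.17), and the proteasome call without young replicates 2 (0.18) and 3 (0.0658). With the ribosomal RNA share as a covariate the fatty acid synthesis (adjusted p 0.0536, camera) and proteasome calls (0.0587) ended, and the former also with library size scaling (0.0533). The erythrocyte call ended without young replicate 1 (adjusted p 0.0624, camera), young replicate 3 (0.0797) and old replicate 2 (0.0894).

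Cytosolic ribosomal protein genes were higher in old than in young liver in 78 of 81 members, with a median of 0.49 (camera adjusted p = 1.08e-08, and adjusted p = 0.634 with an estimated correlation). No member passed edgeR over all genes or adjusted over the list alone. The median was 1.23 without young replicate 1. The library medians, with each gene centred on its mean over all libraries, were 1.04, -0.75 and -0.32 in young replicates 1 to 3 and 1.09, 0.64 and 0.29 in old replicates 1 to 3, and the ribosomal RNA shares were 29.65, 4.52 and 4.74% and 21.98, 15 and 7.07%.

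**Figure D4:**
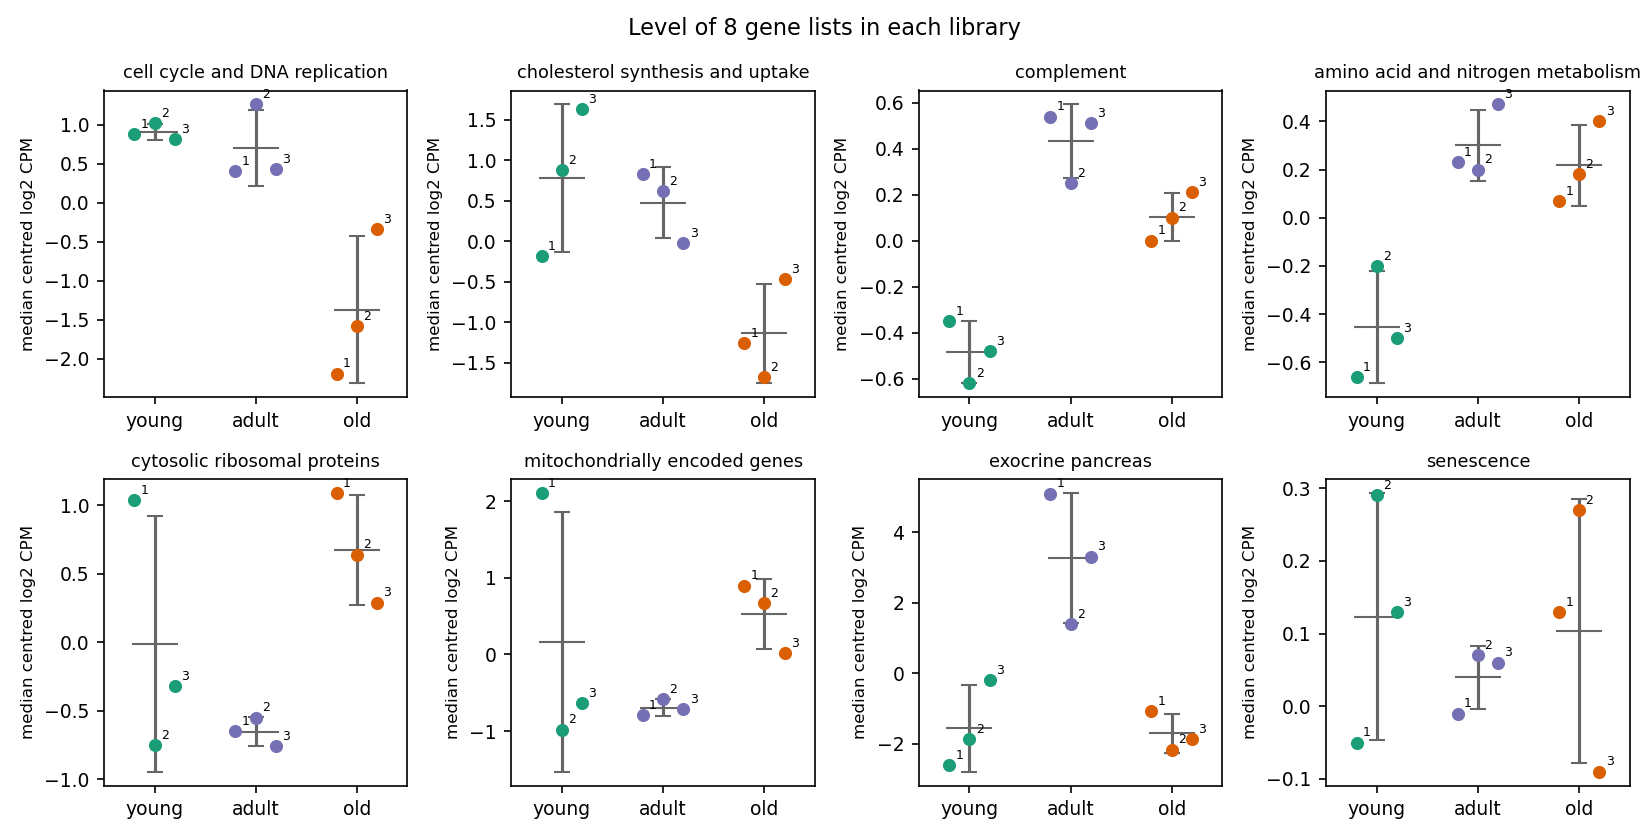
Median of 8 gene lists in each library, as centred log2 CPM, with the mean and SD of each age. Points are numbered by replicate.

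In all, 15 lists changed between young and old in camera, 7 higher and 8 lower, and 0 did with an estimated correlation, while fry called 7. Calls of 11 of these 15 lists held with each library left out.

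Of the 78 genes that changed between young and old, HTRA1B and the aquaporin-9-like gene also changed from young to adult, and ENSNFUG00015017190 from adult to old (-2.15 ± 0.27 between young and old, edgeR adjusted p = 0.0125). The other 75 passed the test in neither step, and no gene passed in both. The number in a step was 843 of 1321 without young replicate 1, 105 without old replicate 3, 8 without adult replicate 2, 2 without young replicate 3 or adult replicate 1, 1 without adult replicate 3, and 0 without old replicate 1 or 2. At an adjusted p under 0.10 in the steps (edgeR), 9 of the 78 were in the first step alone, 34 in the second alone and 1 in both. The adult and old comparisons share the young libraries. Across genes their log2 fold changes correlated at r = 0.253, against 0.494 ± 0.0112 (SD, 20 simulations) in simulated data with no change between ages. Their covariance was 0.434, against 0.407 ± 0.0147 in those simulations. Part of any overlap may come from the shared samples.

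The study's title concerns markers of senescence, and their genes were tested by name. CDKN1A (ENSNFUG00015005973), the p21 cell cycle inhibitor, had 9.51 ± 8.23 CPM in young, 5.42 ± 0.0998 in adult and 57.2 ± 26.96 in old fish (n = 3 each). Its log2 fold change was 2.60 ± 0.62 between young and old (edgeR adjusted p = 0.095) and 3.40 ± 0.64 between adult and old (0.0761). Without young replicate 1 the adjusted p was 0.00916 between young and old in edgeR, with a range over its alternatives of 0.00144 to 0.274. Between adult and old it was 0.0102 in edgeR without young replicate 1 and 0.0136 without any young library, with a range of 1.09e-05 to 0.454. The proliferation marker mki67 had 4.28 ± 2.80, 4.66 ± 1.53 and 0.464 ± 0.804 CPM in young, adult and old fish (old against young -3.16 ± 1.34, edgeR adjusted p = 0.301). The replication clamp gene pcna had 131 ± 108, 110 ± 59.7 and 22.6 ± 17.9 CPM (-2.54 ± 0.96, edgeR adjusted p = 0.251). The lamin gene lmnb1, which is lost in many senescent cells, had 4.11 ± 5.40, 1.72 ± 0.375 and 0.464 ± 0.718 CPM (-3.16 ± 1.44, edgeR adjusted p = 0.338). GLB1, the lysosomal beta-galactosidase, had -0.49 ± 0.52 between young and old (edgeR adjusted p = 0.719), and HMGB2A, a chromatin protein, -0.68 ± 0.35 (0.399). The matrix protease gene mmp9 had 0.50 ± 1.32 (edgeR adjusted p = 0.903), and the IGF-binding protein genes igfbp1 and IGFBP1A had -0.54 ± 1.00 (0.85) and 4.45 ± 1.16 (0.115). IGFBP1A had a log2 fold change of 7.345 without young replicate 1 (edgeR adjusted p 0.00647, with a range over its alternatives of 0.000571 to 0.304), and its young libraries had 5.57, 0.155 and 0.386 CPM. No gene matched the symbols cdkn2a, cdkn2b, il6 or il1b among those tested.

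Senescence as a gene list did not pass the test in any comparison. The 32 senescence genes had medians of -0.02, 0.05 and 0.02 for adult against young, old against adult and old against young (camera adjusted p = 0.954, 0.826 and 0.832). Adjusted over the list alone 3 were higher and 2 lower between young and old, against 1 lower over all genes. The 37 genes of the senescence-associated secretory phenotype had medians of -0.04, -0.29 and -0.07 (camera adjusted p = 0.348, 0.542 and 0.988). In the same order of comparisons, apoptosis genes (30) had medians of -0.19, -0.03 and -0.13 (camera adjusted p = 0.496, 0.821 and 0.916). Oxidative stress genes (34) had -0.12, 0 and -0.05 (camera adjusted p = 0.991, 0.948 and 0.889), and heat shock genes (35) had -0.14, -0.36 and -0.37 (0.717, 0.567 and 0.247). Ribosome biogenesis genes (59) had -0.13, -0.3 and -0.28 (camera adjusted p = 0.722, 0.542 and 0.235). Hepatocyte identity genes (37) had 0.15, 0.08 and 0.08 (camera adjusted p = 0.796, 0.542 and 0.421), and cholangiocyte genes (30) had 0.09, 0.17 and 0.14 (0.455, 0.969 and 0.531). Estrogen-responsive genes (12) had 0.48, 0.02 and 0.37 (camera adjusted p = 0.0563, 0.969 and 0.129), and B and plasma cell genes (11) had 0.56, 0.43 and 0.61 (0.105, 0.969 and 0.247). Adipocyte genes (11) had -0.16, -0.38 and 0.06 (camera adjusted p = 0.389, 0.542 and 0.967), and intestine genes (8) had 0.07, 0.38 and 0.29 (0.796, 0.542 and 0.247).

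Several lists that did not pass with all 9 libraries passed with 1 library left out. Without young replicate 1, ribosome biogenesis (adjusted p 0.00198, camera), heat shock (0.0281), cholesterol (0.0281), endoplasmic reticulum stress (0.0281) and proteasome genes (9.47e-07) were lower in adult than in young fish, and estrogen-responsive genes (0.0104) were higher. Ribosome biogenesis (adjusted p 0.00315, camera) and mitochondrial ribosomal protein genes (0.0235) were then lower in old than in young fish, and mitochondrially encoded (7.39e-06) and oxidative phosphorylation genes (0.0235) were higher. B and plasma cell markers were higher in adult than in young fish in 6 of the 9 fits with 1 library left out. These were without young replicate 1 (adjusted p 0.0277, camera), young replicate 3 (0.0326), adult replicate 1 (0.0317), and old replicates 1 (0.0159), 2 (0.0315) and 3 (0.0135). Cell cycle genes were lower in adult than in young fish without adult replicate 2 (adjusted p 0.00302, camera). Pancreatic islet genes were lower in old than in adult fish without adult replicate 2 (adjusted p 6.98e-08, camera) and without old replicate 3 (0.048), and coagulation genes also without old replicate 3 (0.048). Between young and old, mitochondrial ribosomal protein genes were also lower without young replicate 3 (adjusted p 0.0426, camera) and old replicate 1 (0.0449). Without old replicate 2, hepatocyte identity (adjusted p 0.0359, camera), intestine (0.04) and xenobiotic metabolism genes (0.0412) were higher in old than in young fish.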

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

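The voom quality weights, the rRNA share as a covariate, the removal of rRNA and mitochondrial genes and the 2-age fit for lists were chosen after seeing the data, and the other alternatives before. Of the values of genes named as changed, 1328 kept their direction and side of the threshold, 599 lost their call and 0 reversed, and of other named genes 5065 were kept, 562 gained a call and 59 moved. Among the values of changed lists 651 were kept, 138 lost their call and 8 reversed, and of other lists 1062 were kept, 43 gained a call, 153 moved and 3 reversed. Scaling by RLE, upper quartile or TMM without the 20 most abundant genes, a filter at 10 CPM, non-robust edgeR and the removal of rRNA and mitochondrial genes kept the counts of changed genes within 1.5 times. The deposited table held counts, so the alternatives fixed for a table of normalized values only were not run. Depth itself was not varied. In data simulated from these libraries, the old against young test recovered 0, 12, 42 and 60% of genes changed 2, 4, 8 and 16-fold.

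For adult against young, old against adult and old against young, the changed genes were 2, 1 and 78. They were 13, 74 and 131 without a filter on low counts, 397, 1903 and 1129 in DESeq2, 159, 3072 and 972 with quality weights in limma-voom, and 0, 1682 and 6 in edgeR on the 2 ages compared. In adult against young limma-voom called 9, and in old against young glmTreat called 45. With the rRNA share as a covariate edgeR called 0, 2 and 338. With 1 library left out they ran from 0 to 12, from 0 to 1625 and from 2 to 1321. Changed lists were 22, 13 and 15, with an estimated correlation 0, 0 and 0, in fry 9, 6 and 7, and in old against adult 8 with the rRNA covariate. Genes of old against young in a step were 3, at an adjusted p under 0.10 in the steps 44, and with 1 library left out 0 to 843. Old against adult gave 1 gene without young replicate 2 or 3 and 1625 without young replicate 1, where the common coefficient of variation was 0.56 against 0.61. That library is in neither age of this contrast, so it bore on the count through the shared filter, scaling and spread. The cause of the other differences was not tested.

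The direction of these list tests turned in camera with the rRNA share as a covariate, past the threshold or not. The cause was not tested. The shares of adult (2.22 to 2.51%) and old libraries (7.07 to 21.98%) do not overlap, so between these ages the covariate cannot separate the share from age. A call lost or turned there therefore does not decide between them. For the mitochondrially encoded genes the covariate cannot decide, since most of the share is mitochondrial rRNA. In adult against young, cytosolic ribosomal proteins (adjusted p 7.34e-08) and mitochondrially encoded genes (1.06e-06) turned higher in adult, nuclear oxidative phosphorylation (0.492) too, and fatty acid oxidation and PPAR targets (0.0155) turned lower. In old against adult, cytosolic ribosomal proteins (0.879), mitochondrially encoded genes (4.41e-08) and nuclear oxidative phosphorylation (0.0761) turned lower in old, and endoplasmic reticulum stress (0.923), proteasome (0.00955) and ribosome biogenesis (0.048) turned higher. Without young replicate 1 the mitochondrially encoded genes turned higher in adult, and their adjusted p in camera ran from 4.23e-05 to 0.748 with 1 library left out.

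With the replicate number as a replicate block, edgeR called 0, 0 and 45 genes, and 0 genes were in a step, and the fibroblast list lost its call in old against adult (camera adjusted p 0.0556). The labels do not say that equal numbers pair fish, and same-number deviations correlated at -0.05 to 0.21, so the numbers were not taken as pairs. For 7 of 9 libraries the best match in the other ages had the same number, a hint from the data and not from the design, and whether they pair is unresolved.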

Other observations

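Genes annotated to DNA integration were higher as a group in old than in adult liver. Chosen only after results had been seen were the test of gene ontology terms of the deposited table (288 terms with 10 to 300 members), the mislabelling tests and the gene-wise rRNA correlation below, with the list-based test of mislabelling added after the gene-based one. The term DNA integration (105 genes, 4 with a symbol) had a median log2 fold change of 2.38 between adult and old (camera adjusted p = 3.89e-17, and adjusted p = 0.884 with an estimated correlation). It summed to 274.7, 253.1 and 246.8 CPM in the adult libraries, 2063, 1911 and 1118 CPM in the old ones and 1525, 296 and 335.4 CPM in young replicates 1, 2 and 3. In edgeR on all 9 libraries 0 of the 105 members passed between adult and old. On adult and old libraries alone 27 of 83 tested members were higher and 1 lower, in a fit that called 1682 of 13094 genes. With the rRNA share as a covariate the median was 0.28 (camera adjusted p 0.714), while over the libraries left out in turn the adjusted p ran from 1.51e-18 to 8.09e-15. The rRNA shares of adult and old libraries do not overlap, so the covariate cannot separate the share from age here. The term DNA-mediated transposition (22 genes) had a median of 1.37 (camera adjusted p = 0.00559, and adjusted p = 0.884 with an estimated correlation), and of -0.27 with the rRNA covariate (0.739). In edgeR 0 of its 13 members tested on adult and old libraries alone passed, and 0 passed without young replicate 1.

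Genes annotated to DNA duplex unwinding (14) had a median of -3.0 between young and old (camera adjusted p = 6.87e-06, and adjusted p = 0.888 with an estimated correlation) and of -3.23 between adult and old (0.00121, and adjusted p = 0.884 with an estimated correlation). With the rRNA covariate their median was -2.25 between young and old (camera adjusted p 2.32e-05), and -1.59 between adult and old, where the call was lost (0.22). Glucokinase, gck, which traps glucose in the liver, had 25.6, 3646 and 652 CPM in young replicates 1, 2 and 3, 55.66, 96.16 and 1.163 CPM in adult replicates 1, 2 and 3 and 1.02 CPM on average in old fish. Its log2 fold change between young replicates 2 and 3 and old was -11.04 ± 1.73 (edgeR adjusted p = 0.0126), and with all 9 libraries its adjusted p was 0.0684, with a range over its alternatives of 1.33e-08 to 0.34.

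If young replicate 1, which stood apart from the other young libraries, were a mislabelled old fish, it could lie near the old libraries, and its median place was 0.853 (0 at the other young, 1 at the old mean, 1315 genes), where each old library, when left out, lay at 0.555 to 1.12 and the adults at 0.119 to 0.288, which fits. On the lists called without it, 41.2% (7 of 17) put it nearer to young, against 5.6 to 28.6% for old libraries left out, so the lists cannot tell. Cell cycle genes lay at 0.02 (old libraries left out 0.45 to 1.65) and macrophage markers at -1.87 (0.78 to 1.49). Amino acid genes lay at -0.55 (0.65 and 0.91 for old replicates 1 and 2, with no call without old replicate 3). Others lay beyond the old mean, among them oxidative phosphorylation (3.43), mitochondrially encoded (2.18), ribosome biogenesis (1.79) and proteasome genes (1.4). The centred median of the gene ontology term DNA replication was -0.15 in this library, 1.12 and 1.21 in young replicates 2 and 3 and -1.41 to -0.56 in old ones. Some genes put young replicate 1 with young, among them HTRA1B (1.201 CPM, old 331.4 to 502.1), fgf19 (0, old 53.07 to 57.14), lck (0.0546, old 11.64 to 17.71) and IGF1 (5.40, old 26.89 to 36), named after their values were seen. All of these passed the old against young test with this library counted as young. HTRA1B, fgf19 and lck were also named for no overlap between young and old libraries. The choice of genes thus favoured this placement, so they cannot weigh against mislabelling, which is not settled by these values. RNA quality could also fit, since the difference of young replicate 1 from the other young libraries correlated at 0.216 across genes with old replicate 1 minus old replicate 3 (at most 0.141 with differences between adults). Lower library complexity is argued against by 16248 expected genes at matched depth, within the 15608 to 16579 of the other libraries, and a difference of this 1 fish was not tested.

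Cell cycle and DNA replication genes were lower in old than in young fish. Loss of low-abundance genes in the old libraries could lower them, but their median of -2.0 lay at percentile 0 of 10000 lists matched on expression (lowest -0.75), which argues against it. RNA quality that goes with the rRNA share might lower them. With that share as a covariate the old against young median was -1.75 (-2.02 to -1.3, list members resampled). By itself this argues against an effect that follows that share as the whole explanation for old against young, but it does not exclude it. Most of that share is mitochondrial rRNA, and it is not a direct measure of RNA quality. The covariate therefore cannot decide about RNA quality itself. The slope within young rests on replicate 1 (29.65% against 4.52 and 4.74%), and within old the list median fell as the share rose. The gene ontology term cell division went from -0.7 to -0.35 (camera adjusted p 0.151), while DNA replication, from -1.48 to -0.94, kept its call (1.06e-07). For old against adult RNA quality is also left open. There the list kept its call with the covariate (camera adjusted p 3.14e-08). DNA replication went from a median of -1.44 to -0.22 (0.271) and cell division from -0.48 to -0.13 (0.762). Age itself stays an untested explanation.

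Cytosolic ribosomal protein genes were higher in old than in adult fish. With the rRNA share as a covariate their median went from 1.37 to -0.08 (-0.13 to -0.02, list members resampled). The shares of adult (2.22 to 2.51%) and old libraries (7.07 to 21.98%) do not overlap. RNA quality and age therefore cannot be told apart, and either may explain the rise. A gain of short transcripts might raise them, and lists matched on expression and length also rose, with a median of 0.55. The ribosomal median lay at percentile 100 of 10000 such lists (highest 0.86), which argues against such a gain as the whole explanation.

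Regrouping the 6 libraries of a comparison gives 10 splits, too few for a share under 0.05. For adult against young 1 of 10 splits, the real one, called as many genes (2, highest other 0) and 1 as many lists (22, highest other 18). For old against adult 1 called as many genes (1, highest other 0) and 2 as many lists (13, highest other 15). For old against young 2 called as many genes (78, highest other 682) and 1 as many lists (15, highest other 11). The split with 682 set young replicate 1 and old replicates 1 and 2 against the other 3, and points to structure among the samples other than age. Of 100 regroupings into 3 ages, the real one included, 3 had as many genes in a step as the real one (3, highest other 469). That share is under 0.05 and by itself argues against chance for that number. But the number in a step ran from 0 to 843 with 1 library left out, and a regrouping with 469 also points to structure among the samples. Chance is therefore not excluded.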
